A study of Mus musculus with 14 samples.

How the data were processed

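Polyadenylated RNA from neck skin of mice labelled female was sequenced in 14 libraries that fall into 5 groups. Untreated wild-type skin gave 2 libraries. Skin treated with MC903 (calcipotriol, a vitamin D analogue that causes dermatitis) for 6 days, 1 nmol in 100 µL a day, gave the other 12. Of these, 3 came from mice injected with an isotype control antibody and 3 from mice injected with MAR1, an antibody against the alpha chain of the IgE receptor FcεRI that is used to deplete basophils. Each of these mice received 20 µg per injection, with 3 injections before MC903 and further ones every other day. The other 6 libraries, from mice without injections, were 3 of Il4ra fl/fl mice and 3 of Pdgfra-Cre Il4ra fl/fl mice (cKO), in which the receptor gene is deleted in Pdgfra-expressing cells such as fibroblasts. Tissue was frozen and cryosectioned before the RNA was extracted. By their titles the untreated libraries were normal skin, while the protocol text also mentions a vehicle control, so whether vehicle was applied to them is not stated. Their library names differ only by a suffix, and whether they came from different mice is not stated.

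The deposited table holds estimated counts per gene symbol (expected counts, with decimals), which were not normalized by the authors. The submitters' processing notes name Salmon 1.2.1, DESeq2 1.44.0 and the genome build GRCm39, without saying which made the table. The table has 35328 entries, of which 1 carries no gene name. That entry was left out of the library sizes and tests. Of the 35327 gene symbols, 31682 were found in a GENCODE M21 annotation. That annotation is on an older genome build, so no coordinates are given. Counts were rounded to whole numbers for the fits. Near-identical gene copies share reads, so values of Hmga1b, the Lce3, Skint, Hba and Hbb genes, the major urinary protein genes and the olfactory receptors cannot be assigned to single copies with certainty.

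All 14 libraries entered 1 fit of 5 group means in edgeR 4.0.16 (R 4.3.3), with TMM scaling, genes kept by filterByExpr and the robust quasi-likelihood test, two-sided. This left 20939 genes, a common dispersion of 0.361 and 9 residual degrees of freedom. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within each comparison. The contrasts were tested in this way, the last of them an interaction, the cKO effect minus the MAR1 effect. Gene levels are given as CPM (counts scaled by library size with TMM in edgeR, mean ± SD), log2 fold changes as estimate ± SE. The SE of a log2 fold change was derived from the test, as its size divided by the square root of the F statistic. It fails for genes near 0 counts (11931.47 for Zfp978 in the interaction). The p-values measure only the spread between these samples. That spread is estimated per gene over all 5 groups, so a p-value does not measure the spread of the compared groups alone. The groups differed in this. Between 2 libraries of a group, the chi-square of the counts per degree of freedom was 57.09 to 85.01 with isotype and 507.7 to 1037 in fl/fl. Floors are 3 counts per library where all libraries of a group had 0 counts, and folds against such a group are given as "at least". They cover counting error only, since no molecular identifiers were used.

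Fixed before the data were examined were the comparisons, 29 gene lists of cell types and pathways, the other settings to try and the rule for named genes. The lists were tested with camera in limma 3.58.1 (preset correlation 0.01, adjusted over the 29 lists) and again with an estimated correlation. The estimated correlation was used with the main fit only, so list and set calls under other settings rest on the preset one. Under those settings the direction of a camera call was not recorded. A median that changed sign there and passed the threshold therefore does not show a call in the opposite direction. Where a count of called members is given without the count over the list alone, both were equal. By the rule, the text names Il4ra and the basophil list in each comparison. It names up to 10 of the largest called increases and decreases among genes with a mean of at least 1 CPM and no overlap between groups, without uncharacterized genes, antibody and T cell receptor segments and pseudogenes. Chance alone separates 3 libraries from 3 others in 10% of genes. It also names up to 4 of the members with the smallest p of each list described. Of the genes so chosen, 3 are not reported here, though they stayed in all fits and lists. Which lists are described was chosen after the list results were seen but before any alternative was run. MC903-induced and MC903-reduced gene sets (called, with a log2 fold change beyond 1 in either direction) were defined in the control arm of the experiment that the tested comparison does not use.

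Olfactory and vomeronasal receptor genes (1376 and 570 in the table), which skin is not known to express at such shares, served as a measure of reads outside the expressed genes. The measure was chosen after the data were seen, as were short lists of salivary gland, red blood cell and Y-linked genes. The other settings fixed before the data were examined were RLE scaling, DESeq2 1.42.0, no filter, a stricter filter (1 CPM in at least 3 libraries), only the groups compared, no untreated libraries, the untreated libraries summed, the replicate number as a block, skeletal muscle and hair follicle scores as covariates (prior count 2), an estimated correlation, no fold minimum for the sets and each library left out. Chosen after seeing the data were the log2 receptor gene share as a covariate, a mean of at least 10 CPM, thinning of all libraries to the shallowest, and the removal of libraries with a high receptor gene share, Y-linked, salivary gland or B cell transcripts.

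The fit was tested on simulated data with the dispersion of these libraries. Only 66 or 67 genes were changed at each fold, up or down at random, without background reads, other tissue or a shift in composition. The shares and false calls below therefore do not carry over to comparisons in which 10270 or 3906 genes were called. In MAR1 against isotype it recovered 2.99% of genes changed 2-fold, 46.3% of those changed 4-fold and 90.9% of those changed 16-fold, with 4 false calls among 19118 genes tested. In cKO against fl/fl the shares were 0%, 28.4% and 84.8%, with 3 false calls among 19789. Relative to TMM, RLE scaling moved the median log2 fold change of all genes by 0.59 in MAR1 against isotype, by 0.12 in cKO against fl/fl and by -0.46 in the interaction, so changes are relative to TMM and list medians smaller than these shifts have no fixed direction. Figures were drawn with matplotlib 3.10.9.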

Results

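Bulk RNA sequencing measured gene expression in mouse neck skin, as estimated counts per gene, in 2 untreated libraries and in 4 groups of 3 libraries each after 6 days of MC903. The groups were isotype control, MAR1, Il4ra fl/fl (fl/fl) and Pdgfra-Cre Il4ra fl/fl (cKO). Library totals, in M counts (mega), were 55.3 and 37.5 in untreated skin, 34.9, 35.6 and 34.3 with isotype antibody and 47.2, 48 and 45.1 in fl/fl mice. They were 25.9, 30.8 and 16.5 in cKO mice and 10.6, 8.74 and 5.78 in the libraries labelled MAR1.

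The libraries also differed in the RNA they held. Olfactory and vomeronasal receptor genes took 6.88% ± 2.77 (SD, n = 3) of counts in the MAR1 libraries and 1.51% ± 1.06 (n = 3) in the cKO libraries. The shares were 0.369% ± 0.089 with isotype, 0.0581% ± 0.0163 in fl/fl (n = 3 each) and 0.163% ± 0.161 in untreated skin (n = 2). Mitochondrial transcripts took 0.238% ± 0.107 of counts with MAR1 against 2.19% ± 0.115 with isotype, and 1.6% ± 1.07 in cKO against 3.26% ± 0.948 in fl/fl. Skeletal muscle genes took 6.31%, 2.16% and 1.31% of counts in the fl/fl libraries and at most 0.479% in a cKO library. The salivary protein gene Bpifa2 reached 733 and 10950 CPM in fl/fl libraries 1 and 2, against 0.118 CPM in the remaining one. The Y-linked genes Ddx3y and Eif2s3y stood at 69.95 and 53.46 CPM in cKO library 1 and at 0 in the other cKO libraries, although all mice were labelled female. Whether that label holds for cKO library 1 was not settled, so a difference in sex may enter the cKO comparison.

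**Figure D1:**
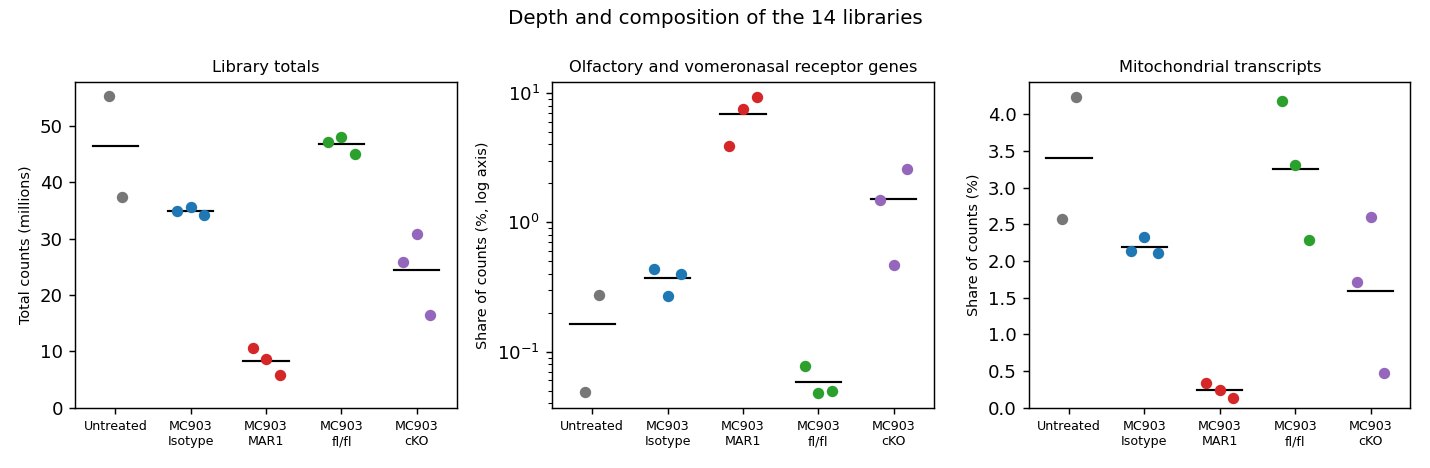
Total counts in M, share of counts on olfactory and vomeronasal receptor genes in percent (log axis) and share of mitochondrial transcripts in percent for the libraries of each group, with points for libraries and lines for group means. The MAR1 libraries hold 5.78 to 10.6 M counts and receptor gene shares of 3.86% to 9.29%.

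Isotype-treated MC903 skin was compared with untreated skin to describe the response to MC903. The isotype mice had also been injected with antibody, so the changes cannot be ascribed to MC903 alone. Cyp24a1, the vitamin D 24-hydroxylase that the vitamin D receptor induces, stood at 4290 ± 490 CPM (n = 3) after MC903, against 1 count in the 2 untreated libraries together (adjusted p = 0.00017, edgeR). The cytokine Tslp, made by keratinocytes and known to be induced by MC903, rose 148-fold (log2 7.21 ± 1.08, 382 ± 170 against 2.58 ± 0.72 CPM, adjusted p = 0.0054). Stfa3, a cysteine protease inhibitor, rose 295-fold to 776 ± 130 CPM (adjusted p = 0.00017). Krt77, a keratin, fell from 5780 ± 3900 to 21.5 ± 4.1 CPM, 269-fold (adjusted p = 0.011), and Skint5, of a gene family expressed in skin and thymus epithelium, fell 241-fold to 0.23 ± 0.12 CPM (adjusted p = 0.00038).

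In that comparison 644 genes changed, 283 up and 361 down (3759 at an unadjusted p under 0.05). Late cornified envelope genes were among the largest increases. Lce3d reached 103 ± 42 CPM against 0 counts in untreated skin, at least 1660-fold higher (adjusted p = 0.0039), Lce3e was at least 618-fold, Lce3b at least 459-fold and Lce3a at least 254-fold higher. The other large increases were those of Akr1d1, a steroid reductase (at least 4420-fold, adjusted p = 0.0065), Cstdc6 (at least 548-fold), Spink12 (at least 499-fold), the peptidase gene Ecel1 (at least 444-fold) and Tchhl1 (at least 354-fold). Krt19, a keratin, fell 111-fold (adjusted p = 0.0022), Serpina3b, a serpin gene, fell 123-fold (adjusted p = 0.0062) and Mup16, a major urinary protein, fell 478-fold (adjusted p = 0.024). Ky, Rtl3, Pon1 and P2rx2 had 2 or 3 counts in all isotype libraries together, against 17.1, 5.5, 8.12 and 9.84 CPM in untreated skin, and Hamp2 stood at 0.185 against 60 CPM (adjusted p = 0.05).

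Of 28 keratinocyte stress genes tested, 16 rose and none fell (27 rose adjusted over the list alone). Their median log2 fold change was 6.74, or 6.4 with genes absent from untreated skin at their bound (camera adjusted p = 2.9e-39, and 0.076 with an estimated correlation). Gjb6, which encodes a connexin, rose 113-fold (log2 6.82 ± 0.97) and the antimicrobial peptide gene Defb14 went from 1 count to 19.4 ± 8.6 CPM. Of 10 vitamin D receptor targets 4 rose (6 over the list alone, median 2.49, adjusted p = 4.2e-08, and 0.076 with an estimated correlation), among them S100g, a calcium-binding protein (13-fold), and the carbonic anhydrase gene Car2 (12.8-fold). Of 20 cell division genes 7 rose (16 over the list alone, median 1.53, adjusted p = 3.9e-12, and 0.086 with an estimated correlation), with Cdk1 4.17-fold, Mki67 3.82-fold, Kif11 3.99-fold and Birc5 2.99-fold higher. Of 22 inflammatory cytokine genes 5 rose (6 over the list alone, median 1.31, 1.14 with bounds, adjusted p = 0.0012, and 0.086 with an estimated correlation), including Il36a (68.3-fold), Il36b (28.9-fold), Il6 (5.71-fold) and Il24 (at least 116-fold).

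Mast cell and basophil genes were higher after MC903. Of 12 mast cell genes 3 rose (10 adjusted over the list alone, median 1.87, adjusted p = 2.4e-08, and 0.086 with an estimated correlation). They were Mrgprb1 (4.33-fold), the tryptase gene Tpsb2 (4.69-fold) and Hdc, the enzyme that makes histamine (9.54-fold). Of 12 basophil genes, a list that shares Hdc and 3 others with the mast cell list, 3 rose (9 over the list alone, median 1.57, adjusted p = 1.4e-06, and 0.086 with an estimated correlation). Mcpt8, a basophil protease, rose 36.3-fold (5.03 ± 1.5 against 0.142 ± 0.2 CPM, adjusted p = 0.025). The log2 fold changes of basophil list genes that did not pass were 4.74 for Fcer1a, 1.91 for Cd200r3, 1.62 for Cpa3, 1.51 for Ms4a2, 1.32 for Cyp11a1, 1.25 for Prss34, 1.07 for Gata2, 1.02 for Itga2 and -0.79 for Il4. Kit, a receptor of mast cells, was at 1.3 (adjusted p = 0.082) and Il4ra at 1.21 ± 0.65 (adjusted p = 0.34).

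Fibroblast, fat, interferon and dendritic cell genes were lower. Of 21 dermal fibroblast genes 7 fell (17 adjusted over the list alone, median -2.32, adjusted p = 2.7e-15, and 0.086 with an estimated correlation), including Pi16 (11.9-fold), Sfrp2 (30.6-fold), Cd34 (5.9-fold) and Dpt (9.68-fold). Of 14 adipocyte genes 7 fell (10 over the list alone, median -2.36, adjusted p = 2.4e-13, and 0.086 with an estimated correlation). Plin1, which coats lipid droplets, fell 25.8-fold, the beta-3 adrenergic receptor gene Adrb3 19.3-fold, the hormone gene Adipoq 11.8-fold and Cfd 8.97-fold. Of 22 interferon response genes 6 fell (19 over the list alone, median -2.32, adjusted p = 4.6e-15, and 0.17 with an estimated correlation), with Ifit3 14.4-fold, Isg15 15.6-fold, Oasl2 8.29-fold and Irf7 8.93-fold lower. Of 16 dendritic cell genes 5 fell (1 rose and 7 fell over the list alone, median -1.53, adjusted p = 3.1e-06, and 0.24 with an estimated correlation), among them Cd207, which encodes langerin (17.7-fold), Mgl2 (8.8-fold), Cd209a (8.8-fold) and the MHC class II gene H2-Ab1 (8.76-fold). Skeletal muscle genes, which took 0.285% and 2.28% of counts in the untreated libraries and 0.244% ± 0.0327 with isotype, had a median of -2.34. The count of changed genes depended on which libraries were kept. It was 116 without untreated library 1, 108, 110 and 132 without isotype libraries 1, 2 and 3, and 619 without untreated library 2. The count was also far lower with the untreated libraries summed, and far higher with DESeq2 or with only these groups in the fit, as given below. Of the 29 lists 21 were called, 12 up and 9 down, and none with an estimated correlation, where the lowest adjusted p was 0.076.

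The second MC903 comparison set fl/fl skin against the same untreated libraries. These are wild-type, so the groups differ in genotype too, and perhaps in batch, and the changes cannot be ascribed to MC903 alone. Cyp24a1 stood at 4440 ± 5300 CPM (n = 3) against 1 count in untreated skin (adjusted p = 0.00016), Tslp rose 299-fold to 771 ± 460 CPM (log2 8.22 ± 1.13, adjusted p = 0.0045), and Krt16, a keratin of stressed epidermis, rose 361-fold to 6710 ± 6600 CPM (adjusted p = 0.0045). Skint5 fell 65.7-fold (adjusted p = 0.0016), and Lce1m, a late cornified envelope gene, fell 65.9-fold (adjusted p = 0.0051). In all, 161 genes rose and 199 fell, 360 together (3837 at an unadjusted p under 0.05). Of the 29 lists 13 were called up and 5 down, none with an estimated correlation (lowest adjusted p = 0.052).

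Of the keratinocyte stress genes 17 of 28 rose (25 over the list alone, median 6.6, 6.42 with bounds, adjusted p = 2e-45, and 0.052 with an estimated correlation). Stfa3 rose 322-fold, Lce3d was at least 990-fold and Lce3e at least 306-fold higher, and Defb14 went from 1 count to 18.5 ± 19 CPM. Akr1d1 (at least 3630-fold), Ecel1 (at least 644-fold) and Cstdc6 (at least 374-fold) were again absent from untreated skin. Of the vitamin D receptor targets 3 of 10 rose (5 over the list alone, median 1.76, adjusted p = 6.5e-07, and 0.056 with an estimated correlation), S100g by 41.1-fold, while Slc34a2 stood at 4.32-fold (adjusted p = 0.089). Of the cell division genes 6 of 20 rose (18 over the list alone, median 1.54, adjusted p = 2.3e-19, and 0.052 with an estimated correlation), with Birc5 4.39-fold, Cdk1 3.77-fold, Mcm5 4.23-fold and Rrm2 2.82-fold higher. Mcpt8 rose 46.2-fold (adjusted p = 0.026), and Il6 (5.46-fold, adjusted p = 0.054), Hdc (4.54-fold, 0.11) and Fcer1a (12.5-fold, 0.19) did not pass.

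Of the 21 dermal fibroblast genes only Prrx1, a transcription factor gene, fell (2.82-fold, adjusted p = 0.036, 9 fell over the list alone). The list median was -1.44 (adjusted p = 6.8e-09, and 0.24 with an estimated correlation), with Dcn at -1.46, Col1a2 at -2.56 and Dpp4 at -1.67. Further decreases were those of Skint7 (46.7-fold), Skint6 (30.3-fold), Skint10 (20-fold), Krt19 (46.1-fold), Slc23a1 (50.2-fold), Cpz (26.7-fold), the growth factor gene Fgf9 (18.6-fold) and Akr1c19 (at least 48.2-fold). B and plasma cell genes had a median of 6.21 with none of 10 called in edgeR (7 over the list alone, adjusted p = 0.00037, and 0.45 with an estimated correlation). Cd79a, Cd22 and Pax5 had log2 fold changes of 8.84, 6.33 and 8.02 (adjusted p = 0.084, 0.099 and 0.11). The B cell share of counts was 0.221%, 0.0508% and 0.000238% in the 3 fl/fl libraries. Absent from untreated skin were the lymphocyte genes Fcmr (37.2 ± 45 CPM, at least 599-fold), Pou2af1 (20.4 ± 25, at least 328-fold) and Izumo1r (18.7 ± 27, at least 301-fold) and the cardiac myosin light chain gene Myl7 (38.8 ± 59, at least 624-fold). The count of 360 was 736 without untreated library 1 and 65 without untreated library 2, and 0 genes were called by edgeR with only these groups in the fit (1892 at an unadjusted p under 0.05, against 2124 called by DESeq2 on all libraries).

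**Figure D2:**
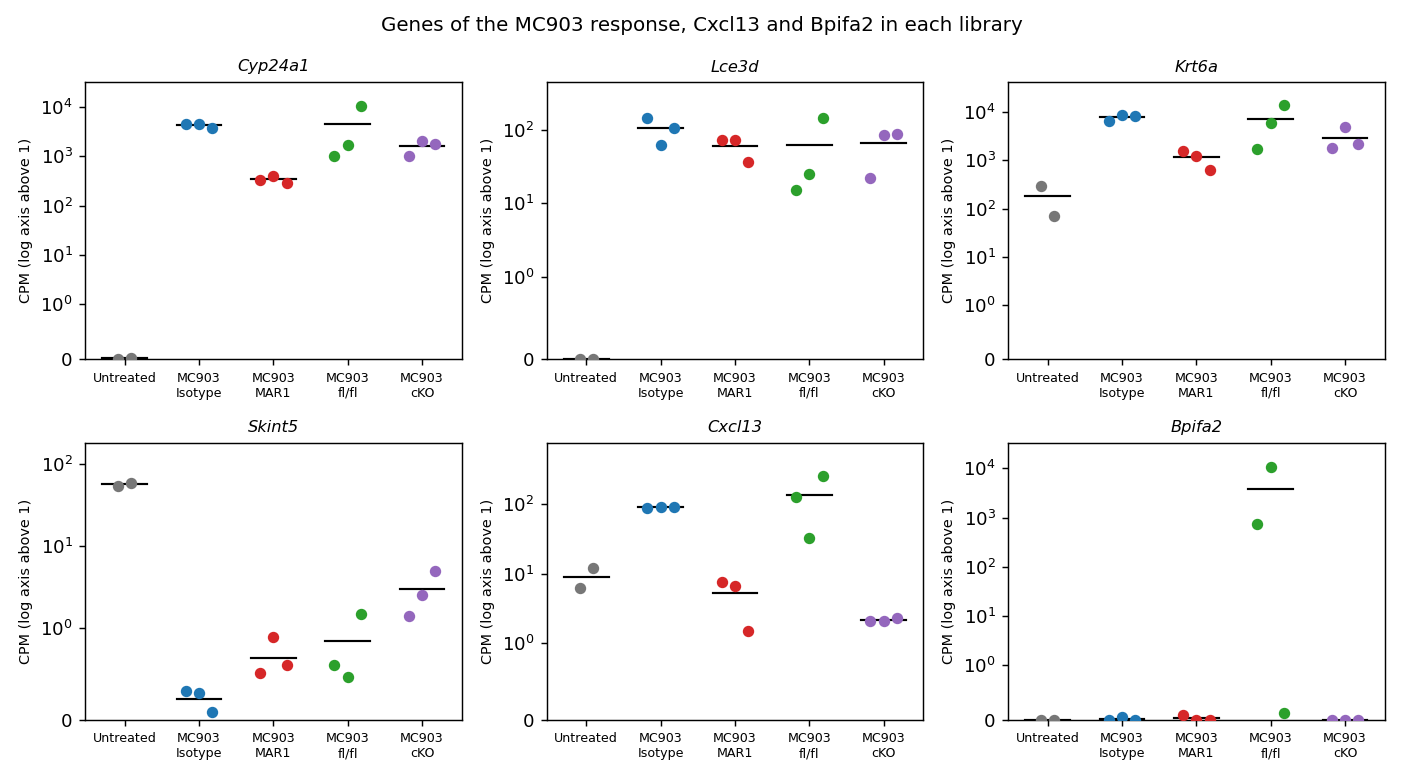
Levels of Cyp24a1, Lce3d, Krt6a, Skint5, Cxcl13 and Bpifa2 in CPM (log axis above 1) in the libraries of each group, with points for libraries and lines for group means. Bpifa2 is at 733 and 10950 CPM in fl/fl libraries 1 and 2, and Cxcl13 is between 2.06 and 2.3 CPM in the cKO libraries.

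The MC903-treated control arms, fl/fl and isotype, differed in genotype, injections and experiment, and their comparison shows how far the controls of both experiments lie apart. Skeletal muscle, B cell and T cell genes and single haemoglobin genes were higher in fl/fl. Mylpf, a fast muscle myosin light chain, was 62.5-fold higher (log2 5.97 ± 1.38, 2970 ± 3700 against 47.5 ± 13 CPM, n = 3 each, adjusted p = 0.038). The haemoglobin gene Hbb-bs was 59.9-fold higher (log2 5.9 ± 0.96, 3090 ± 3200 against 51.6 ± 26 CPM, adjusted p = 0.023) and Ighm, the antibody mu chain gene, 98.3-fold higher (log2 6.62 ± 1.43, adjusted p = 0.035). Il4ra did not differ past the threshold (log2 -0.08 ± 0.56, adjusted p = 0.96).

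Of 1094 genes that differed, 262 were higher and 832 lower in fl/fl (5079 at an unadjusted p under 0.05), with 9 lists up and 3 down. Of 18 skeletal muscle genes 5 were higher (13 adjusted over the list alone, median 3.76, adjusted p = 1.4e-11, and 0.63 with an estimated correlation), among them Myh2 (6.39-fold), Eno3 (25.9-fold) and Mb, the myoglobin gene (15-fold). Of 10 B and plasma cell genes 5 were higher (10 over the list alone, median 6.2, adjusted p = 2.9e-05, and 0.63 with an estimated correlation), with Cd79b 259-fold and Cd22 52.9-fold higher. Of 20 T cell genes 5 were higher (16 over the list alone, median 2.97, adjusted p = 1.4e-07, and 0.63 with an estimated correlation), with Cd3d 39.8-fold, Trac 42.1-fold, Cd6 33.2-fold and Cd247 17.6-fold. Other large differences were those of Hbb-bt (63.1-fold), Hba-a2 (51-fold), Hba-a1 (50.5-fold), Dhrs7c (66.1-fold), Sypl2 (61.8-fold) and Bpifa2 (3890 ± 6100 CPM against 2 counts). Ky and Rtl3 stood at 11.4 and 2.02 CPM against 2 counts each.

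Lower in fl/fl were receptor genes, 142 of 666 tested with none higher, including Or6c88 (at least 87.6-fold), Or1f19 and Or11n2 (at least 66.6-fold each) and Vmn2r10 (at least 37.9-fold). Foxa3 (at least 60.8-fold), Semp2l2b (at least 60.6-fold), Tafa2 (at least 55.1-fold), Corin (at least 49.9-fold), Wt1 (at least 42.6-fold) and Anks1b (at least 37.9-fold) were also absent from the fl/fl libraries. Cd200r3, an activating receptor of basophils and mast cells, was 6.02-fold lower (3.07 ± 0.36 against 18.5 ± 4.6 CPM, adjusted p = 0.035), while Mcpt8 (log2 0.35), Fcer1a (-1.1) and Il6 (-0.07) did not pass. The count of 1094 changed strongly when any 1 library was left out. It was 6, 55 and 6 genes without isotype libraries 1, 2 and 3, 77 without fl/fl library 1 and 3176 without fl/fl library 3. It was 0 by edgeR without fl/fl library 2 (4213 at an unadjusted p under 0.05, with 3396 by DESeq2 on all libraries). With only these groups in the fit the count was also lower, as given below. Without fl/fl libraries 1 and 2 it was 1, and the T cell gene Trac and the B cell gene Ighm turned to log2 -2.07 and -1.96.

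MAR1 was compared with isotype control to ask what basophil depletion does in MC903-treated skin. Genes of the high-affinity IgE receptor were lower in the libraries labelled MAR1. Fcer1a, the chain the antibody binds, fell 11.8-fold (log2 -3.57 ± 1.19, 2.43 ± 2.7 against 29.6 ± 5.2 CPM, n = 3 each, adjusted p = 0.026) and Ms4a2, its beta chain, fell 4.59-fold (adjusted p = 0.0045). Cpa3, a protease of mast cells and basophils, fell 12.2-fold (16 ± 8.2 against 196 ± 23 CPM, adjusted p = 0.00043). Mcpt8, a basophil protease, instead rose 5.07-fold (25.5 ± 6.8 against 5.03 ± 1.5 CPM, adjusted p = 0.024) and Cd200r3 rose 14.8-fold (274 ± 66 against 18.5 ± 4.6 CPM, adjusted p = 0.00043). These last genes went against the direction the label implies, so the libraries are named by their label only. With the receptor gene share as a covariate Fcer1a turned to log2 1.28, Mcpt8 to -0.4 and Hdc to 0.09, and the median of the basophil list to 0.03. Ms4a2 (-0.43), Cpa3 (-1.1) and Cd200r3 (0.31) lost their calls without a change of sign, while the median SE of the genes called with MAR1 went from 0.51 to 0.89.

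Of the 12 basophil genes 3 rose and 6 fell (the same counts adjusted over the list alone), with a median of -1.5 that did not pass (adjusted p = 0.64). Hdc fell 5.02-fold, Itga2, an integrin, 3.39-fold and Cyp11a1, a steroid enzyme, 3.51-fold, and Il6 rose 4.06-fold (adjusted p = 0.005). Prss34, another basophil protease, had 4 counts against 31 (adjusted p = 0.47), Il4 stood at log2 0.76 and the transcription factor gene Gata2 at 0.18. Of 12 mast cell genes, 4 of them shared with the basophil list, 9 fell (median -2.15, adjusted p = 0.011, and 0.96 with an estimated correlation), Tpsb2 by 4.31-fold and Mrgprb1 by 2.73-fold. In the same libraries receptor genes took 6.88% of counts against 0.369%, and 464 of 666 rose while 1 fell.

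**Figure D3:**
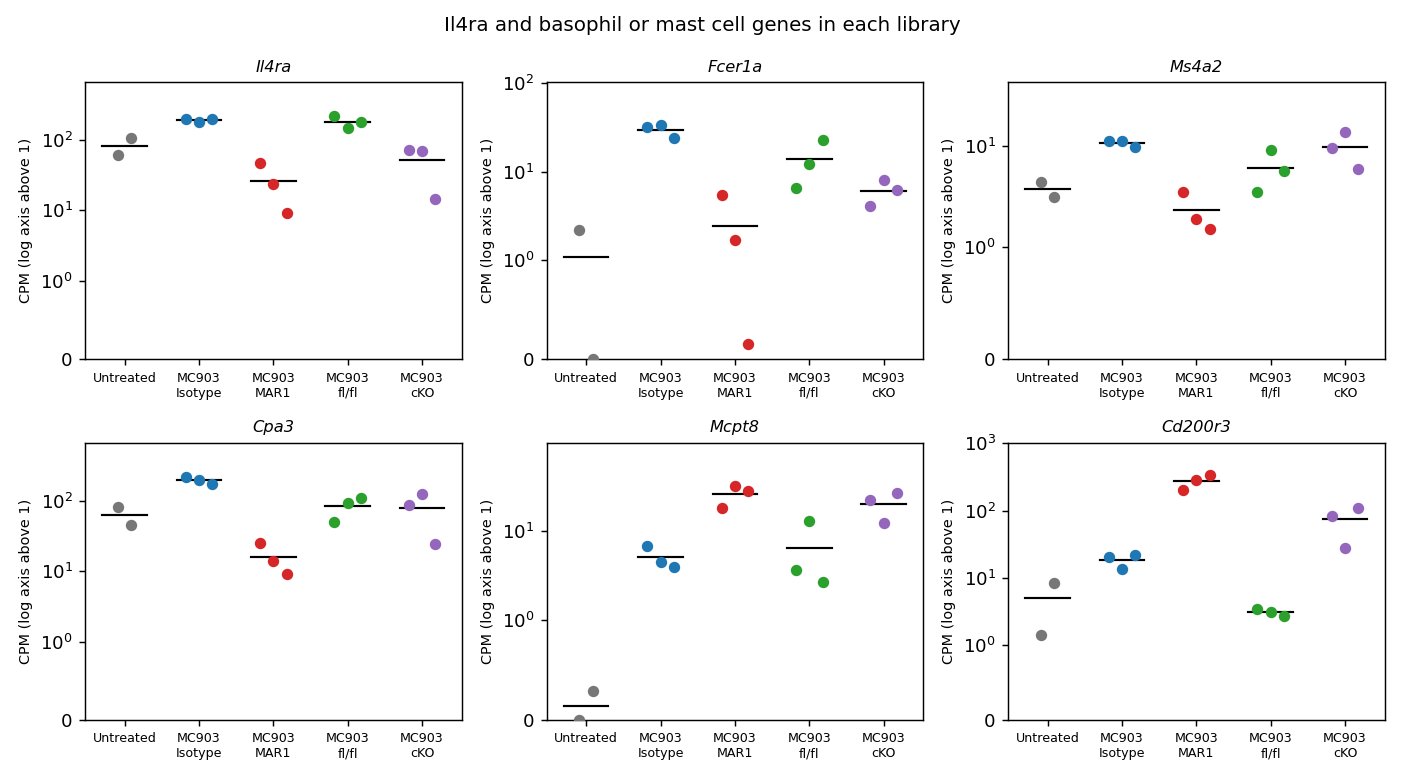
Levels of Il4ra and of the basophil and mast cell genes Fcer1a, Ms4a2, Cpa3, Mcpt8 and Cd200r3 in CPM (log axis above 1) in the libraries of each group, with points for libraries and lines for group means. Cd200r3 lies at 205, 282 and 336 CPM in the MAR1 libraries and Cpa3 at 25, 13.9 and 9.02 CPM.

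Il4ra, the receptor chain shared by IL-4 and IL-13, fell 7.24-fold with MAR1 (log2 -2.86 ± 0.6, 26 ± 19 against 189 ± 9.2 CPM, adjusted p = 0.002). Of 18 type 2 cytokine and receptor genes 6 fell and 1 rose (median -0.82, adjusted p = 0.17). Among them Crlf2, the TSLP receptor, fell 49.7-fold, Stat6, which carries the IL-4 and IL-13 signal, 4.17-fold, and Osmr, the oncostatin M receptor, 3.97-fold. Of 25 genes that IL-4 and IL-13 induce 5 rose and 5 fell (median 0.38, adjusted p = 0.82), with Chil3 16.4-fold, Arg1, the arginase of alternatively activated macrophages, 45.6-fold and Serpinb2 5.48-fold lower and the eosinophil chemokine gene Ccl24 11.8-fold higher. Of 31 chemokine genes 4 rose and 6 fell (4 and 4 over the list alone). Their median was -0.34 and their mean 0 (adjusted p = 0.97), with the median at 0.2 under RLE scaling. Cxcl13, which attracts B cells, fell 17.1-fold (log2 -4.09 ± 0.68, 5.24 ± 3.3 against 90.9 ± 2.6 CPM, adjusted p = 0.00056), Cxcl14 8.76-fold and Cx3cl1 9.18-fold.

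Of 20 monocyte and macrophage genes 4 rose and 9 fell (median -1.34, adjusted p = 0.086), with the complement gene C1qb 14.4-fold, the lysosomal gene Cd68 24.7-fold, Lyve1 30.6-fold and the lipopolysaccharide co-receptor gene Cd14 10.3-fold lower. Of 25 matrix and remodelling genes 14 fell and 3 rose (median -1.44, adjusted p = 0.0089, and 0.96 with an estimated correlation). The proteases Mmp2 and Mmp9 fell 27.5-fold and 27.9-fold and Lox, which crosslinks collagen, 13.3-fold, while the macrophage elastase gene Mmp12 rose 7.67-fold. The secreted protein gene Spp1 fell 4.69-fold. In these libraries mitochondrial transcripts took 0.238% of counts against 2.19%. Of 13 mitochondrial transcripts 9 fell (11 over the list alone, median -2.3, adjusted p = 0.00057, and 0.96 with an estimated correlation), with mt-Co1 131-fold, mt-Cytb 66.6-fold and mt-Co3 and mt-Nd4 18.7-fold each.

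Of 24 epidermal barrier genes 14 fell and 1 rose (median -1.77, adjusted p = 0.011, and 0.99 with an estimated correlation). Among them were Asprv1, a protease of the upper epidermis (32.2-fold), the cornification caspase gene Casp14 (14.2-fold), the barrier lipid enzyme gene Alox12b (24.6-fold) and the corneodesmosome gene Cdsn (21.2-fold). Of 28 keratinocyte stress genes 12 fell and 1 rose (12 fell and none rose over the list alone, median -1.82, adjusted p = 0.045, and 0.99 with an estimated correlation). Sprr1a was 13.8-fold, Lcn2 12.7-fold, Krt17 5.41-fold and Krt6a 6.68-fold lower (1160 ± 480 against 7740 ± 1100 CPM). With the receptor gene share as a covariate the median of this list turned to 0.56 and Krt6a to 0.34. The list passed the threshold there with the preset correlation (camera adjusted p = 0.00029). The direction of that call was not recorded, and an estimated correlation was not run there. Of 10 vitamin D receptor targets 6 fell (7 over the list alone, median -2.33, -1.82 with bounds, adjusted p = 0.031, and 0.96 with an estimated correlation). Cyp24a1 fell 12.5-fold (344 ± 61 against 4290 ± 490 CPM, adjusted p = 0.0016) and Tslp 6.87-fold (55.7 ± 47 against 382 ± 170 CPM, adjusted p = 0.0074). Of 22 interferon response genes 11 rose and 1 fell (12 and 1 over the list alone, median 1.51, adjusted p = 0.013, and 0.99 with an estimated correlation), with Ifit1 15.9-fold, Gbp5 17-fold, Rsad2 6.84-fold and Iigp1 4.96-fold higher (Gbp5 at log2 -0.1 with the covariate). Receptor gene shares of 3.86%, 7.49% and 9.29% and totals of at most 10.6 M counts stood beside these changes in the MAR1 libraries.

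In all, 10270 of 20939 genes changed with MAR1, 4723 up and 5547 down (12034 at an unadjusted p under 0.05). Of the 29 lists 9 were called, 1 up and 8 down, none of them with an estimated correlation (lowest adjusted p = 0.96). The largest increases included Hmga1b (35.3 ± 18 CPM, at least 407-fold), Mup10 (at least 134-fold), Zfp978 (at least 86.9-fold), the antimicrobial peptide gene Leap2 (at least 25.5-fold) and Ube2srt (25.4 ± 8.5 CPM and 733 counts, against 4 counts with isotype). Fbxw21 (4.31 CPM), Or9a2 (2.66), Ly6g5c (2.41), the sodium channel gene Scn11a (2.32) and Or8b44 (2.08) had 1 or 2 counts with isotype. The largest decreases were Rdh16f1 (0 counts against 84 ± 29 CPM, at least 249-fold), Srp54b (at least 172-fold), the protocadherin gene Pcdhgc3 (at least 74.1-fold), the small heat shock protein gene Hspb6 (at least 31.6-fold), Zfp968 (at least 24.8-fold), Rpp38 (at least 22.2-fold), Adnp (at least 22-fold), Il11ra2 (at least 19.2-fold), Arl11 (at least 19.1-fold) and Clip3 (at least 17.7-fold). With the log2 receptor gene share as a covariate 0 genes were called by edgeR (1537 at an unadjusted p under 0.05, with 91.6% of the variance of this share between groups), and Zfp978, Fbxw21, Ly6g5c and Zfp968 changed sign (log2 -1.66, -5.15, -0.84 and 1.47). Without MAR1 libraries 2 and 3 the count was 2409, with Il4ra at log2 -2.04 (adjusted p = 0.096). Calls of Fcer1a and Mcpt8 were each lost without isotype library 2, MAR1 library 2 or MAR1 library 3, that of Fcer1a also without isotype library 1 and that of Mcpt8 also without isotype library 3, where its log2 fold change was 2.2 (adjusted p = 0.081).

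The cKO and fl/fl groups were compared to ask what loss of Il4ra in Pdgfra-expressing cells does in MC903-treated skin. Il4ra itself stood at 70.7, 67.9 and 14.5 CPM in the cKO libraries and at 215, 145 and 176 CPM in the fl/fl libraries, 3.5-fold lower (log2 -1.81 ± 0.57, n = 3 each, adjusted p = 0.043). Il4ra also fell with MAR1 (log2 -2.86), in mice without the deletion. The difference of the effects did not pass (1.05 ± 0.79, edgeR adjusted p = 0.4). Receptor gene shares were higher in both, at 6.88% with MAR1 and 1.51% in cKO, against 0.369% and 0.0581% in their controls. The decrease in cKO alone therefore does not show the deletion. Counts per gene cannot show which part of Il4ra is deleted, or in which cells. Cxcl13 fell 64.3-fold (log2 -6.01 ± 0.74, 2.15 ± 0.13 against 138 ± 110 CPM, adjusted p = 0.0021). Tslp fell 5.9-fold (131 ± 68 against 771 ± 460 CPM, adjusted p = 0.026), and Il13ra2, the IL-13 decoy receptor, rose 2.53-fold (20.4 ± 1.5 against 8.06 ± 0.36 CPM, adjusted p = 0.033).

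Of 18 type 2 cytokine and receptor genes 2 rose and 3 fell (3 and 4 over the list alone, median -0.13 and mean 0.1, adjusted p = 0.34, and median 0.57 without fl/fl libraries 1 and 2). Il2rg, the common gamma chain, fell 6.42-fold and Il5ra, the IL-5 receptor, rose 8.77-fold (log2 -1.13 with the receptor gene share as a covariate, adjusted p = 0.83). Of 25 genes induced by IL-4 and IL-13 5 fell and 1 rose (median -0.49, adjusted p = 0.093, and median 1.12 without fl/fl libraries 1 and 2). Cish and Socs1, inhibitors of cytokine signals, fell 4.02-fold and 4.31-fold, Ccl22 fell 15-fold and Fcer2a, the low-affinity IgE receptor of B cells, 191-fold. Of 31 chemokine genes 5 fell (4 over the list alone, median -0.99, adjusted p = 0.0029, and 0.91 with an estimated correlation), Ccl5 by 206-fold and Ccl6 by 3.27-fold. Without fl/fl libraries 1 and 2, which carried salivary gland and B cell transcripts, the chemokine median turned to 0.79 (adjusted p = 0.76), Il2rg to 0.96, Socs1 to 0.26, Ccl22 to 0.79 and Fcer2a to 5.18 on the log2 scale. With the 1 fl/fl library left, Cish (-1.41), Ccl5 (-0.33), Ccl6 (-1.25) and the monocyte and macrophage list (median -0.23) kept their direction but not their calls. Of 20 monocyte and macrophage genes 8 fell (1 rose and 9 fell over the list alone, median -0.99, adjusted p = 0.00083, and 0.85 with an estimated correlation), with Lyve1 6.78-fold, C1qb 3.61-fold, Cd68 5.73-fold and the lysozyme gene Lyz2 3.59-fold lower. Of 13 mitochondrial transcripts 5 fell (8 over the list alone, median -1.83, adjusted p = 3.9e-06, and 0.85 with an estimated correlation), with mt-Atp8 6.08-fold, mt-Nd4 5.02-fold, mt-Nd2 3.81-fold and mt-Nd4l 2.9-fold lower.

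Of 21 dermal fibroblast genes 5 fell (median -0.33, adjusted p = 0.057, and 0.91 with an estimated correlation, and median 0.62 without fl/fl libraries 1 and 2). Mfap5, a microfibril protein, fell 5.69-fold (log2 -2.51 ± 0.52, adjusted p = 0.006), the complement gene C3 3.63-fold, Dpt, a matrix protein, 6.04-fold and the Wnt modulator Sfrp2 8.96-fold. Without fl/fl libraries 1 and 2 these decreases were smaller, at log2 -1.21 for Mfap5, -0.81 for C3, -1.15 for Dpt and -0.96 for Sfrp2. The basophil list held 1 called gene of 12, Cd200r3, which rose 24.1-fold (74.3 ± 42 against 3.07 ± 0.36 CPM, adjusted p = 0.0021) while the receptor gene share was 1.51% against 0.0581% and 388 of 666 receptor genes rose with none lower. The other log2 fold changes were 1.65 for Mcpt8 (adjusted p = 0.14), 1.26 for Il4, 1.13 for Gata2, 0.76 for Il6, 0.69 for Ms4a2, 0.37 for Cyp11a1, 0 for Itga2, -0.06 for Prss34, -0.11 for Cpa3, -0.2 for Hdc and -1.19 for Fcer1a. Of 8 melanocyte genes 2 rose (3 over the list alone, median 1.57, adjusted p = 0.019, and 0.85 with an estimated correlation), the pigment enzyme genes Dct (4.79-fold) and Tyr (5.62-fold, but log2 -0.88 with the receptor gene share as a covariate, adjusted p = 0.72), while Oca2 (log2 4.12, adjusted p = 0.057) and Mlana (1.87, 0.1) did not pass. Without fl/fl libraries 1 and 2 the melanocyte median was 1.28, with Dct at log2 2.03 and Tyr at 3.32.

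Skeletal muscle, B cell and T cell genes were lower in cKO, and the same lists were higher in fl/fl than in isotype skin. Of 18 muscle genes 11 fell (17 over the list alone, median -4.34, adjusted p = 1.1e-12, and 0.85 with an estimated correlation), with Mylpf 78.2-fold, Myl1 65.6-fold, Myh2 14.9-fold and Neb 12.2-fold lower, beside muscle shares of 6.31%, 2.16% and 1.31% in fl/fl and 0.479%, 0.00412% and 0.0536% in cKO. Of 10 B and plasma cell genes 6 fell (8 over the list alone, median -5.24, adjusted p = 0.0062, and 0.91 with an estimated correlation), with Igkc 373-fold, Cd79b 179-fold and Ighm 43-fold lower. Of 20 T cell genes 7 fell (9 over the list alone, median -2.8, adjusted p = 0.0069, and 0.91 with an estimated correlation), with Cd6 31.6-fold, Trac 29.4-fold and Lck 13.6-fold lower. Without fl/fl libraries 1 and 2 the T cell median turned to 2.66 and the B cell median to 3.13.

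In all, 3906 genes changed in cKO, 2655 up and 1251 down (7356 at an unadjusted p under 0.05). Of the 29 lists 8 were called, 1 up and 7 down (15 without fl/fl library 3), none with an estimated correlation (lowest adjusted p = 0.85). The largest increases were receptor genes, Or6c88 (30.5 ± 20 CPM, at least 385-fold), Or1f19 (at least 288-fold), Or11n2 (at least 280-fold), Or8a1b (at least 174-fold) and Or52e8 (at least 138-fold), with the transcription factor genes Wt1 (at least 229-fold) and Foxa3 (at least 209-fold), Tafa2 (at least 193-fold), Semp2l2b (at least 173-fold) and Slc22a13 (at least 143-fold). The largest decreases were Bpifa2 (at least 30600-fold, with 733, 10950 and 0.118 CPM in the fl/fl libraries), Mrgprg, a sensory neuron receptor gene (0 counts against 16.6 ± 13 CPM, at least 131-fold, and log2 0.02 with the covariate), Tceal7 (at least 36.9-fold), Gal3st2b (at least 17.1-fold), the IL-12 subunit gene Il12a (at least 16.8-fold), St8sia5 (at least 15.9-fold), Dnase1 (339-fold), the B cell factor gene Spib (188-fold) and Lrrc14b (adjusted p = 0.05). The count was 1958 without cKO library 3, 748 without cKO libraries 1 and 3, 656 without fl/fl libraries 1 and 2, and 14 with the receptor gene share as a covariate. Il4ra lost its call without any one of the 6 libraries (log2 -2.12 to -1.33). Cxcl13 kept its call without cKO libraries 1 and 3 (log2 -5.76, adjusted p = 0.048) and without fl/fl libraries 1 and 2 (-6.6, 0.0018), lost it without all of these (-6.68, 0.065) and with the covariate (-6.32, 0.23). Tslp kept its call without fl/fl library 2 but not without fl/fl library 1 (-2.2, 0.088) or 3 (-1.68, 0.13) or cKO library 1 (-2.18, 0.074), 2 (-2.25, 0.088) or 3 (-2.85, 0.063).

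**Figure D4:**
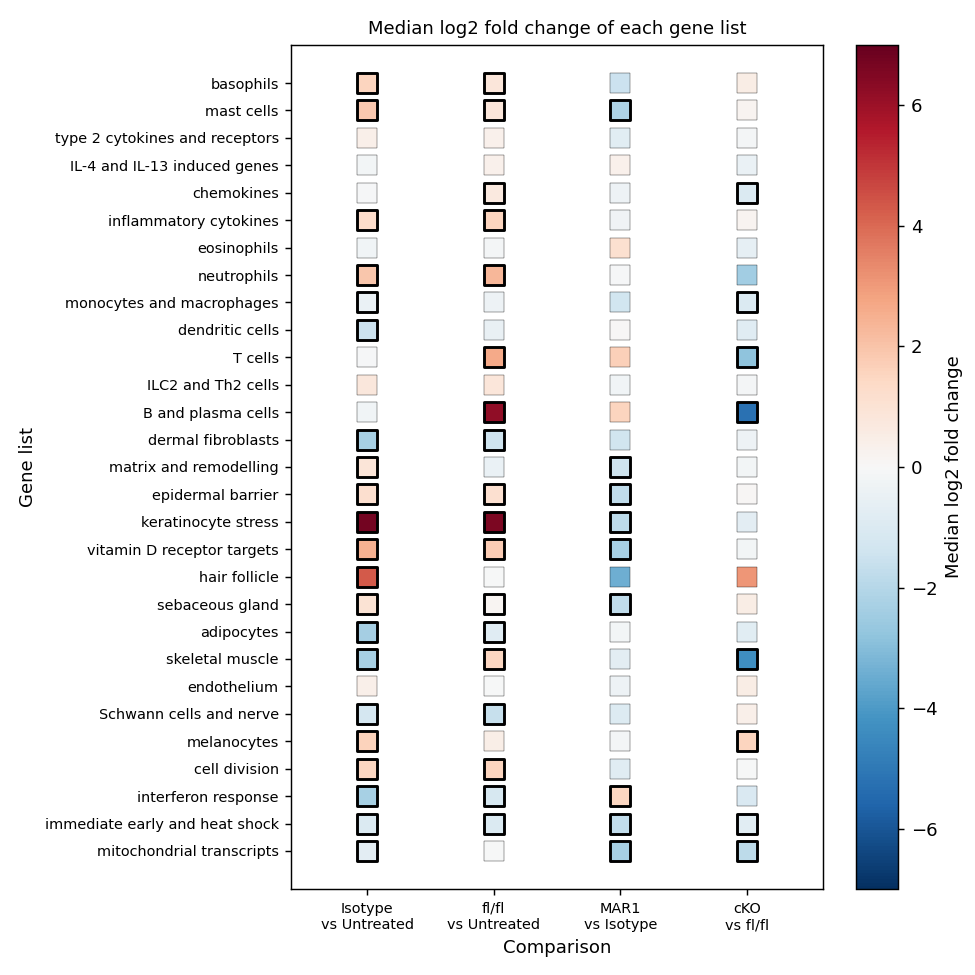
Median log2 fold change (colour) of 29 gene lists (vertical) in 4 comparisons (horizontal), with bold outlines where the camera adjusted p with the preset correlation was under 0.05. Keratinocyte stress genes have medians of 6.74 and 6.6 after MC903 and -1.82 with MAR1, and B and plasma cell genes have 6.21 in fl/fl against untreated skin and -5.24 in cKO against fl/fl.

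Genes changed by MC903 in a control arm were then followed in the other experiment. The set induced in fl/fl skin also held lymphocyte genes such as Fcmr, Pou2af1 and Izumo1r. In refits without 1 library, with covariates, a block, summed untreated libraries or thinning, the sets were defined anew. Their medians there come partly from other genes. Where more than 1 library was removed, the sets of the main fit were kept. The 161 genes induced in fl/fl skin had a median log2 fold change of -1.16 with MAR1, where 72 fell and 12 rose (camera adjusted p = 0.00013, and 0.45 with an estimated correlation), and the 199 reduced genes had a median of 1.41, where 101 rose and 25 fell (adjusted p = 4e-08, and 0.31 with an estimated correlation), in libraries with a receptor gene share of 6.88% against 0.369%. The induced genes lost their call with that share as a covariate (-0.36, adjusted p = 0.52) and the reduced genes with thinned libraries (0.39, 0.14). Without untreated library 2 both calls were lost (-1.02 and 0.27), and without fl/fl library 3 the induced genes were at -0.48 (adjusted p = 0.067). In cKO skin the 283 genes induced with isotype had a median of 0.16 (43 rose, 17 fell, adjusted p = 0.16) and the 361 reduced genes -0.58 (62 fell, 21 rose, adjusted p = 7.7e-05, and 0.45 with an estimated correlation). The reduced genes lost that call without isotype library 1, 2 or 3 (-0.03, 0.07 and -0.06), untreated library 2 (0.18) or fl/fl library 2 (-0.13), with a replicate block (-0.06), the hair follicle covariate (-0.28) or the untreated libraries summed (0.14), and turned to 0.02 without fl/fl library 1 (adjusted p = 0.0045). The induced genes reached 5.75 without untreated library 2, 1.03 without fl/fl library 3 and 0.22 without cKO library 3, each past the threshold, and turned to -0.52 without untreated library 1 (adjusted p = 0.048) and -0.71 with the skeletal muscle covariate (0.0055). Without fl/fl libraries 1 and 2 the medians of both sets changed sign, the induced to -0.16 and the reduced to 0.85. Without cKO libraries 1 and 3 as well, the reduced genes were at 0.7.

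Across the 20939 genes, the effects of MAR1 and of the cKO correlated with Pearson r = 0.583 and Spearman rho = 0.614, where genes are not independent replicates and no p is given. Called in both, 2293 genes were higher (599 expected if the lists were independent) and 710 lower (331), and 20 and 27 genes went opposite ways. Both the MAR1 and the cKO libraries held more receptor gene reads than their controls (6.88% against 0.369% and 1.51% against 0.0581%). Of 666 receptor genes 464 and 388 were called higher. With such a difference in both experiments, the overlap and correlation do not show a shared effect of antibody and deletion. The effects were also tested against each other. They differed for 1667 genes, 1285 with the cKO effect higher (6244 at an unadjusted p under 0.05), a split of 77.1% that was 48.3% under RLE scaling, where MAR1 calls went from 46% to 63.5% higher. The cKO effect lay above the MAR1 effect for Cpa3 (difference 3.51 ± 0.75 on the log2 scale, adjusted p = 0.026), Ms4a2 (2.89 ± 0.73, 0.034) and Cyp11a1 (2.18 ± 0.59, 0.041), which fell with MAR1 and were not called in cKO. The differences of Il4ra (1.05 ± 0.79, adjusted p = 0.4), Cxcl13 (-1.91 ± 0.87, 0.16), Fcer1a (2.38 ± 1.54, 0.32) and Hdc (2.13 ± 0.8, 0.1) did not pass. Leaving out isotype library 1, 2 or 3 left 1 gene each and MAR1 library 3 left 2, against 129 without fl/fl library 2, 502 without cKO library 1, 3292 without cKO library 3 and 4863 without fl/fl library 3.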

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

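The tests of MAR1 libraries inside the isotype range, of cKO against isotype skin, of slopes of Mcpt8 and Cd200r3 and of the other basophil list genes were chosen only after the result was seen.

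Both MC903 responses use the same untreated libraries, which cancel when the responses are subtracted. Their difference is therefore the comparison of fl/fl with isotype skin, with its 1094 genes, and not a separate test. Neither arm had untreated skin of its own, so a difference in the response itself could not be tested. Single genes are listed here because they had been named for either response. Single lymphocyte genes were higher in fl/fl, with log2 differences of 5.73 for Cd22, 5.65 for Fcmr, 4.29 for Pou2af1 and 6.38 for Izumo1r. The B cell share of counts was 0.221%, 0.0508% and 0.000238% in the fl/fl libraries, and Cd22 turned to -1.55 without fl/fl libraries 1 and 2. Some fibroblast and fat genes were higher in fl/fl, 3 of 21 and 2 of 14 (4 and 6 over the list alone). The differences were 2.96 for Sfrp2, 2.17 for Dpt, 2.14 for Pi16 and 2.78 for Plin1. Neither list passed with an estimated correlation (adjusted p = 0.74 and 0.63). Mup16 differed by 8.25, and Ky and Rtl3, with 2 counts each in the isotype libraries, had fitted differences of 8.94 and 6.43 that are no bounds. The mast cell gene Mrgprb1 (-2.07), Cd200r3 (-2.59), Car2 (-1.75), Fgf9 (-4.28) and Slc23a1 (-4.72) were lower in fl/fl. The arms also differed in genotype, injections and experiment, and no explanation was tested for these genes as a group. The count of 1094 changed strongly when any 1 library was left out. It was 6, 55 and 6 genes without isotype libraries 1, 2 and 3 and 77 and 3176 without fl/fl libraries 1 and 3. It was 0 by edgeR without fl/fl library 2 (4213 at an unadjusted p under 0.05). The entry without a gene name, left out of all tests, took 0.678% of counts in the MAR1 libraries and 0.225% in cKO, above the 0.037% in untreated skin.

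With MAR1, 10270 genes were called. A difference in depth is argued against as the whole cause, since thinning every library to the shallowest left 10357 calls. Reads outside the genes that skin expresses are a candidate explanation, because the slope of each gene on the receptor gene share within the untreated, fl/fl and cKO groups correlated across genes with the MAR1 effect (r = 0.621, 0.61 without the receptor genes themselves), where genes are not independent replicates. With the share as a covariate, the median size of these log2 fold changes went from 2.47 to 1 and their median SE from 0.51 to 0.89, so the calls ended through smaller effects and larger errors, and 81% of the genes had the same direction. An effect of the antibody cannot be told apart from the background, because 0 MAR1 libraries lay inside the isotype range of the share and the closest was 8.81-fold above it.

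Skeletal muscle, B cell and T cell genes were lower in cKO than in fl/fl. Other tissue in the fl/fl sections is a candidate explanation for the lymphocyte genes, since in cKO against isotype skin, which uses no fl/fl library, the B cell list median was 0.92 (SD 1.02 between cKO libraries) and the T cell median 0.65 (SD 0.18), not below -1. The cKO libraries also held more receptor gene reads than isotype (1.51% against 0.369%). Both lists had positive medians with MAR1 as well (1.56 and 1.69, neither past the threshold). This test therefore cannot fully separate other tissue in fl/fl from a loss in cKO. For muscle the same test gave -0.73 with an SD of 3.04, so other tissue in fl/fl and a loss in cKO cannot be told apart. The most abundant genes named reached 2970 ± 3700 CPM for Mylpf, 252 ± 350 for Igkc and 3890 ± 6100 for the salivary gene Bpifa2 in fl/fl, and no sort was made that would remove such tissue. An effect of the deletion on lymphocytes or muscle stays open, as untested.

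Mcpt8 and Cd200r3 were higher with MAR1 while Fcer1a, Ms4a2, Hdc and Cpa3 were lower. Whether the MAR1 libraries held more basophils cannot be told, because the other 6 basophil list genes went both ways, with a median log2 fold change of -0.53 (median SE 0.46). Background reads are a candidate explanation for the increase of Cd200r3, since within the untreated, fl/fl and cKO groups its log2 level followed the log2 receptor gene share with a slope of 0.89 (SE 0.09). For Mcpt8, with a slope of 0.62 (SE 0.38), this cannot be told. With the receptor gene share as a covariate Mcpt8 turned to -0.4, and of the genes that fell Fcer1a turned to 1.28 and Hdc to 0.09, none past the threshold. The call of Mcpt8 was lost without isotype library 2 (log2 2.26), isotype library 3 (2.2), MAR1 library 2 (2.21) or MAR1 library 3 (2.3), and that of Fcer1a without isotype library 1 (-3.51) or 2 (-3.48) or MAR1 library 2 (-3.27) or 3 (-3.04). Depletion of basophils, which the label names, stays open, as does a loss of mast cells, which share Cpa3, Hdc, Fcer1a and Ms4a2.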

How the results depend on the processing

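The receptor gene share as a covariate, the mean of at least 10 CPM, thinning and the removal of more than 1 library were chosen only after the result was seen, and the other tests were planned. Thinning every library to the shallowest left the MAR1 count within 1.5 times its value, so depth limits it little. The count of fl/fl against isotype, which also changed when any 1 library was left out, went from 1094 to 31. The count of MAR1 genes stayed within 1.5 times of 10270 under each planned setting and without each library (7341 to 12222), and Cxcl13 kept its call in both experiments under each planned setting and without each library. For every count, list total, set and correlation below that moved, the cause was not tested, except that removed libraries and stricter filters leave fewer samples or genes to call. Counts are of genes called, list and set values are median log2 fold changes, gene values are log2 fold changes, and the genes and lists given are among those that changed sign. The MC903 sets were defined anew in each refit, except where more than 1 library was removed. List and set calls here rest on the preset correlation, unless an estimated one is named. Numbers in the titles did not pair the libraries, with correlations of residuals between equal numbers of -0.144 to 0.0771.

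Under RLE scaling the interaction count was 904 (1667 in the report), the chemokine median with MAR1 was 0.2, and Prss34 and Itga2 in cKO were 0.1 and 0.13. Of the single genes, lists and counts of higher or lower genes, 323 stayed the same, whether called or not, while 6 lost and 2 gained a call. Without a filter the correlation of the effects was 0.48 and the MC903-induced genes in cKO, at 0.22, passed the threshold (adjusted p = 0.018). With the stricter filter the correlation was 0.694, the chemokine median with MAR1 0.15 and Itga2 in cKO 0. With DESeq2 the counts were 5994 in cKO, 2214 for isotype and 2124 for fl/fl against untreated skin, 3396 for fl/fl against isotype and 3730 for the interaction, the correlation was 0.411, and Prss34 and Itga2 in cKO were 0.09 and 0.12.

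With only the groups compared the counts were 1409 in cKO, 3553 for isotype and 0 for fl/fl against untreated skin (1892 at an unadjusted p under 0.05), 455 for fl/fl against isotype and 998 for the interaction. The correlation was 0.664, the chemokine median with MAR1 0.16, and Prss34, Cpa3 and Itga2 in cKO were 0.11, 0.03 and 0.15. The MC903 sets gave no value for MAR1 there, because no fl/fl gene was called. Without the untreated libraries the interaction count was 998, the correlation 0.664, the chemokine median 0.28, and Prss34 and Itga2 in cKO were 0.1 and 0.14. With the untreated libraries summed the counts against untreated skin were 50 for isotype and 549 for fl/fl, and the MC903-induced and reduced genes in cKO were at -0.15 and 0.14, neither past the threshold.

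With a replicate block the counts were 253 and 224 for isotype and fl/fl against untreated skin, 175 for fl/fl against isotype and 537 for the interaction, and the MC903-reduced genes in cKO were at -0.06 and lost their call (adjusted p = 0.4). With the skeletal muscle covariate the counts were 1788 in cKO, 411 for isotype against untreated skin, 545 for fl/fl against isotype and 0 for the interaction in edgeR (3546 at an unadjusted p under 0.05). There 5 lists were called in cKO, the median of IL-4 and IL-13 induced genes in cKO was 0.4, the MC903-induced genes in cKO passed at -0.71 (adjusted p = 0.0055), Prss34 in cKO was 0.71 and Mcpt8 in fl/fl against isotype -0.38. With the hair follicle covariate the counts were 2494 in cKO, 242 for isotype against untreated skin and 53 for fl/fl against isotype, the correlation was 0.506, the MC903-reduced genes in cKO were at -0.28 and lost their call (adjusted p = 0.15), and Il6 in fl/fl against isotype was 0.01. With an estimated correlation 0 lists were called by camera in either experiment, and the MC903 sets kept their medians of -1.16 and 1.41 with MAR1 and -0.58 in cKO without passing (adjusted p = 0.45, 0.31 and 0.45). No fold minimum for the sets left the same genes in them, since every called gene had a log2 fold change beyond 1.

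With the receptor gene share as a covariate, which varied mostly between groups, the counts were 0 with MAR1 in edgeR (1537 at an unadjusted p under 0.05), 14 in cKO, 63 for fl/fl against isotype and 3782 for the interaction, 15 lists were called in cKO and the correlation was 0.648. The MC903-induced genes were at -0.36 with MAR1 (adjusted p = 0.52) and passed at 1.45 in cKO. With MAR1 the values were -0.4 for Mcpt8, 1.28 for Fcer1a, 0.09 for Hdc, -1.66 for Zfp978, -5.15 for Fbxw21, -0.84 for Ly6g5c, 1.47 for Zfp968, 0.34 for Krt6a and -0.1 for Gbp5, and the medians 0.03 for basophils, 0.12 for chemokines, 0.56 for keratinocyte stress and 0.82 for immediate early and heat shock genes, both past the threshold (adjusted p = 0.00029 and 0.0012). In cKO they were -1.38 for Mcpt8, 1.53 for Prss34, 4.86 for Fcer1a, 2.55 for Hdc, 2.53 for Cpa3, 0.15 for Itga2, 0.02 for Mrgprg, -1.13 for Il5ra and -0.88 for Tyr, and the medians 0.18 for type 2 cytokines and receptors, 0.2 for dermal fibroblasts and 1.67 for immediate early and heat shock genes, the last past the threshold (adjusted p = 2.9e-06). Against untreated skin fl/fl stood at 0.7 for Cd200r3 and -0.28 for Cpa3, and against isotype at 0.15 for Il6.

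At a mean of at least 10 CPM the counts were 6644 with MAR1, 2206 in cKO and 259 for fl/fl against isotype, with 2 lists called with MAR1 and 4 in cKO, the chemokine median with MAR1 0.09, and the MC903-induced genes in cKO at 0.17 past the threshold. Thinned libraries gave 31 genes for fl/fl against isotype, a correlation of 0.663, MC903-reduced genes with MAR1 at 0.39 (adjusted p = 0.14), a chemokine median with MAR1 of 0.14, Itga2 in fl/fl against untreated skin at 0.14, and Il4 and Il6 in fl/fl against isotype at 0.53 and 0.19. Where a group kept 1 library, that library was taken to vary like the other groups. Without MAR1 libraries 2 and 3 the count was 2409, 4 lists were called, the chemokine median was 0.21 and Prss34 0.21. Without cKO libraries 1 and 3 the count was 748, 13 lists were called, the MC903-induced genes passed at 0.72, the medians were 0.17 for type 2 cytokines and receptors and 0.33 for dermal fibroblasts, and Hdc, Cpa3 and Itga2 were 0, 0.9 and 0.47.

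Without fl/fl libraries 1 and 2 the counts were 656 in cKO, 982 for fl/fl against untreated skin and 1 for fl/fl against isotype, and the MC903-induced and reduced genes in cKO passed at -0.16 and 0.85 (adjusted p = 1.9e-05 and 0.0028). In cKO the medians were 0.57 for type 2 cytokines and receptors, 1.12 for IL-4 and IL-13 induced genes, 0.79 for chemokines, 2.66 for T cells and 3.13 for B and plasma cells, both past the threshold (adjusted p = 1.8e-05 and 0.03), and 0.62 for dermal fibroblasts. The genes were 1 for Prss34, 0.13 for Itga2, 0.96 for Il2rg, 0.79 for Ccl22, 5.18 for Fcer2a, 0.26 for Socs1, 1.73 for Cd6, 2.57 for Trac, 1.91 for Lck, 3.12 for Igkc, 0.61 for Cd79b and 3.14 for Ighm, the last past the threshold (adjusted p = 0.033). Against untreated skin fl/fl stood at -1.56 for Cd79a, -0.69 for Cd22 and -5.29 for Pax5. Against isotype it stood at -1.2 for Mcpt8, -0.45 for Cd247, -1.42 for Cd3d, -2.07 for Trac, -1.67 for Cd6, -1.96 for Ighm, -0.06 for Cd79b and -1.55 for Cd22. Without these and cKO libraries 1 and 3, the cKO count was 2, 14 lists were called, and the MC903-induced and reduced genes were at 0.01 and 0.7, past the threshold. The medians were 0.57 for type 2 cytokines and receptors, 0.96 for IL-4 and IL-13 induced genes, 0.37 for chemokines, 2.09 for T cells, 2.66 for B and plasma cells and 1.2 for dermal fibroblasts, these last 3 past the threshold (adjusted p = 7.3e-06, 0.041 and 0.041), and the genes 0.16 for Prss34, 0.46 for Cpa3, 0.24 for Itga2, 1.54 for Il2rg, 0.37 for Ccl22, 5.67 for Fcer2a, 0.58 for Socs1, 1.99 for Cd6, 2.19 for Trac, 0.82 for Lck, 2.77 for Igkc, 1.55 for Cd79b and 2.74 for Ighm.

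Leaving out each library in turn gave 108 (isotype 1) to 619 genes for isotype against untreated skin, also 110 and 132 without isotype 2 and 3 and 116 without untreated 1. It gave 65 (untreated 2) to 736 (untreated 1) for fl/fl against untreated skin, 1958 (cKO 3) to 4362 in cKO, 0 (fl/fl 2) to 3176 (fl/fl 3) for fl/fl against isotype, with 6, 55 and 6 without isotype 1 to 3 and 77 without fl/fl 1, and 1 (each isotype library) to 4863 (fl/fl 3) for the interaction, with 2 without MAR1 3, 129 without fl/fl 2, 502 without cKO 1 and 3292 without cKO 3. The correlation ranged from 0.46 to 0.632, and the lists called in cKO from 7 to 15 (fl/fl 3). The MC903-induced genes ranged from -1.55 to -0.48 with MAR1 and from -0.52 to 5.75 in cKO, the reduced genes from 0.27 to 4.25 and from -0.68 to 0.18, with the highest values of the reduced genes with MAR1 without untreated 1 and of the induced genes in cKO without untreated 2. With MAR1 the ranges were -0.35 to 0.45 for Gata2 and -0.52 to 0.09 for the chemokine median. In cKO they were -0.47 to 0.73 for Prss34, -0.69 to 0.52 for Hdc, -0.21 to 0.51 for Cpa3 and -0.09 to 0.49 for Itga2, and for the medians -0.27 to 0.29 for type 2 cytokines and receptors, -0.79 to 0.06 for IL-4 and IL-13 induced genes and -0.36 to 0.04 for dermal fibroblasts. Cd200r3 in fl/fl against untreated skin ranged from -1.47 to 1.12, and in fl/fl against isotype Il4ra ranged from -0.58 to 0.05, Mcpt8 from -0.68 to 0.61 and Il6 from -0.51 to 0.13.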

Other observations

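The splits of the libraries reported here were planned, and the tests on salivary gland, red blood cell and Y-linked genes were chosen only after the result was seen.

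With MAR1, further cell type lists moved in different ways. Of 12 sebaceous gland genes 8 fell (median -1.8, adjusted p = 0.013, and 0.96 with an estimated correlation), and of 16 immediate early and heat shock genes 8 fell (9 over the list alone, median -1.75, adjusted p = 0.013, and 0.99 with an estimated correlation). With the receptor gene share as a covariate the immediate early median was 0.82, past the threshold by the preset correlation only (camera adjusted p = 0.0012). The direction of that call was not recorded. Of 21 dermal fibroblast genes 11 fell and 3 rose (median -1.37, adjusted p = 0.16) and of 20 cell division genes 8 fell and 1 rose (7 and 1 over the list alone, median -0.84, adjusted p = 0.16). Of 20 T cell genes 4 rose and 2 fell (3 and 0 over the list alone, median 1.69, adjusted p = 0.23), and eosinophil genes had a median of 1.13 with 2 of 9 higher (1 over the list alone, adjusted p = 0.37). The other lists, each with an adjusted p of at least 0.53, had medians of 1.56 for B and plasma cells, -3.42 for hair follicle (-2.41 with bounds), -0.98 for Schwann cells and nerve and -0.72 for skeletal muscle. Medians smaller than the scaling shift of 0.59 were -0.33 for endothelium, -0.3 for inflammatory cytokines (mean 0.13), -0.22 for ILC2 and Th2 cells (mean 0.07), -0.17 for adipocytes, -0.14 for melanocytes (mean 0.05), -0.06 for neutrophils and 0.05 for dendritic cells.

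In cKO, 16 immediate early and heat shock genes had a median of -0.78 with 3 lower (adjusted p = 0.012, and 0.91 with an estimated correlation). With the covariate that median was 1.67, past the threshold by the preset correlation only (camera adjusted p = 2.9e-06), again in a direction not recorded. The 14 neutrophil genes had a median of -2.46 (-1.82 with bounds) with 1 higher (adjusted p = 0.05, and 0.85 with an estimated correlation). Adipocyte genes had a median of -0.81 (1 of 14 lower and 0 over the list alone, adjusted p = 0.056), dendritic cell genes -0.86 (1 of 16 higher and 3 lower, 1 and 5 over the list alone, adjusted p = 0.093), interferon response genes -1.05 (1 of 22 higher and 2 lower, 0 and 1 over the list alone, adjusted p = 0.12) and keratinocyte stress genes -0.74 (1 of 28 lower and 0 over the list alone, adjusted p = 0.25). The basophil list had a median of 0.53 (adjusted p = 0.23) and the mast cell list 0.2 with a mean of -0.11 (0 of 12 called by edgeR, adjusted p = 0.98). Medians of the remaining lists, none of which passed, were 3.07 for hair follicle (2.84 with bounds), 0.53 for endothelium, 0.51 for sebaceous gland, 0.42 for Schwann cells and nerve, 0.18 for inflammatory cytokines, 0.06 for epidermal barrier (mean -0.19), -0.01 for cell division (mean 0.03), -0.16 for ILC2 and Th2 cells, -0.18 for matrix and remodelling, -0.19 for vitamin D receptor targets and -0.65 for eosinophils.

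After MC903 in the isotype arm, 4 of 25 matrix and remodelling genes rose and 1 fell (10 and 3 over the list alone, median 0.91, adjusted p = 0.014, and 0.45 with an estimated correlation), 2 of 24 epidermal barrier genes rose (8 rose and 1 fell over the list alone, median 1.2, adjusted p = 3e-04, and 0.49 with an estimated correlation) and 5 of 12 sebaceous gland genes rose (6 rose and 1 fell over the list alone, median 1.02, adjusted p = 0.0012, and 0.23 with an estimated correlation). Neutrophil genes had medians of 1.93 with isotype (0 of 14 called by edgeR and 4 higher over the list alone, adjusted p = 0.011, and 0.1 with an estimated correlation) and 2.35 in fl/fl (0 called by edgeR, adjusted p = 0.003, and 0.094 with an estimated correlation). Schwann cell and nerve genes had medians of -1.21 and -1.63, with 1 and 0 of 11 lower in edgeR and 3 and 8 over the list alone (adjusted p = 0.0023 and 2.4e-05, and 0.31 and 0.24 with an estimated correlation).

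The Y-linked genes did not move together. Ddx3y stood at 69.95 CPM and Eif2s3y at 53.46 CPM in cKO library 1 and at no more than 0.7812 CPM in any other library. Uty and Kdm5d stood at 352.5, 447.1 and 549.3 CPM and at 18.13, 57.78 and 70.34 CPM in the MAR1 libraries, where Ddx3y and Eif2s3y had 0 counts. The salivary gene Smr3a had 359 and 5916 CPM in fl/fl libraries 1 and 2 and 0 counts in every other library except untreated library 1 (0.3899 CPM). Haemoglobin genes took 1.26%, 0.307% and 0.181% of counts in the fl/fl libraries and 0.0165% ± 0.0102 in cKO.

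Other splits of the same libraries were counted for each comparison of 3 against 3, where 10 splits are too few for a share under 0.05. The real split of MAR1 and isotype called 10270 genes and the highest other 0 in edgeR, that of cKO and fl/fl 3906 and 6, and that of fl/fl and isotype 1094 and 0, each with 1 split as large, the real one. For the lists, 5 splits called as many as the 9 with MAR1 (highest other 13) and 8 as many as the 8 in cKO (highest other 16). For the size of the set medians, 1 split reached the 1.157 of the MC903-induced genes with MAR1 (highest other 0.691), 1 the 1.413 of the reduced genes (0.741), 8 the 0.163 of the induced genes in cKO (0.802) and 2 the 0.576 of the reduced genes (0.678). Over 40 splits of both experiments, 7 gave as many interaction genes as the 1667 of the real split and the highest other 6683. The other 6 of these all kept the MAR1 and isotype groups and so still held the difference between them. The 21 splits of both experiments and the 9 that kept only cKO and fl/fl gave 0 genes in edgeR. Such a mixed pool is no plain test of chance, and chance is not excluded. For the correlation of 0.583, 2 of 40 splits of the same pool were as large, the real one among them (highest other 0.598). Chance is not excluded there either.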
